A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

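RNA of the budding yeast Saccharomyces cerevisiae was compared on 12 two-colour arrays. On each array the RNA of a treated culture and the RNA of a control culture of the same strain were labelled with the dyes Cy3 and Cy5 and hybridised together. The 4 groups are the wild type and the snf1 deletion mutant at alkaline pH (4 arrays each), and the wild type and the snf1 mutant at low glucose (2 arrays each). Per the labels, 8 µg of total RNA went into an indirect dUTP labelling primed with oligo(dT). The treated sample carried Cy3 on as many arrays of a group as it carried Cy5.

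The deposited values are one log ratio of treated over control per spot and array, taken here as log2, since the base is not stated in the sources used here. The largest value, 7.475, is 178-fold as log2 and 1763-fold as a natural logarithm, and the latter exceeds the 655-fold span between the authors' minimum of 100 units and the 16-bit maximum of 65535. The direction, treated over control, is likely but not stated: it follows the order of the titles, and arrays of opposite dye orientation correlated positively across genes, with a lowest Pearson coefficient of 0.539 over 36 pairs. Per the labels, the authors left out spots under 120 µm in diameter or under 100 fluorescence units in Cy3 and Cy5. The normalization is not given in the sources used here. Array medians lay between -0.065 and 0.112, so each array appears centred, and no further normalization was applied in the comparisons.

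The deposited table has 6212 rows, of which 355 held no value on any array. Systematic names were matched to the locus tags of the R64 annotation for 5662 rows and not for 550. Among the 5857 rows with a value, 4908 have a standard gene name. No gene had more than 1 row, and 2980 genes had a value on all 12 arrays. Arrays give no counts, so their number limits the precision. Genes with near-identical sequence, such as HXT6 and HXT7, the ENA genes and many pairs of ribosomal protein genes, may share signal on spotted probes, and the probe sequences were not examined.

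Before the data were examined, the comparisons, the 28 gene lists, the rule for named genes and most alternatives were fixed. Log ratios of all 12 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as 4 group means plus a gene-specific dye term. Group means were tested against 0 and the difference of the genotypes (snf1 minus wild type) was tested within each treatment, with two-sided p-values adjusted by Benjamini-Hochberg over the genes tested and called under 0.05. A gene was tested where at least 3 of 4 arrays (alkaline pH) or both arrays (low glucose) of each group compared gave a value. The fit pools the spread over all arrays, with 4.56 prior degrees of freedom, so that the groups of 2 arrays borrow their spread from the others. For 52 genes tested in wild type at low glucose no residual degrees of freedom were left and the spread is the prior alone.

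Gene lists with at least 3 measured members were tested with limma's cameraPR at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with a correlation estimated per list from the residuals. Negative estimates, those of the lists of hexose uptake at low glucose, glucose signalling and phosphate, were set to 0, a choice made after they were seen. This is under the preset value, so for these lists the repeat is no stricter test. For the lists of sucrose and maltose use, galactose use and transport at high glucose no correlation could be estimated. The lists cover hexose uptake at low and at high glucose, gluconeogenesis with the glyoxylate cycle, fatty acid oxidation, sucrose and maltose use, galactose use, glucose signalling, glycolysis, the tricarboxylic acid cycle, oxidative phosphorylation, trehalose and glycogen metabolism, general stress, oxidative stress, the calcineurin response, phosphate, iron, copper, the vacuolar proton pump, the cell wall, cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, mitochondrial ribosomal proteins, the proteasome, amino acid synthesis, sulfur with methionine, ergosterol and histones.

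The named genes are the 10 called genes with a standard name and the largest change in each direction for the wild type at alkaline pH, the wild type at low glucose and the genotype difference at alkaline pH, and 5 in each direction for the other comparisons. They had to share a sign on every array of a group or, for a difference, not to overlap between genotypes. To these the rule adds up to 4 called members of each list and 17 preset genes: SNF1, ENA1, PHO84, PHO89, HXT1, HXT2, HXT7, HXK1, HXK2, ADH2, SUC2, HSP12, TPS1, CIT1, FBP1, MIG1 and MIG2. Other list members were named after their values were seen. Printed errors are SDs over arrays for a mean and SEs of limma for a difference.

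Overlaps between called genes were tested with a two-sided Fisher exact test over genes, and medians per array with an exact two-sided permutation test. Alternatives left out the dye term, fitted only the arrays of a comparison, centred the arrays, scaled them to one spread (limma's normalizeMedianAbsValues on centred values), changed the minimum of values per gene, used a robust eBayes, called genes by fold, averaged consecutive arrays, entered the replicate number as a block, or left out each array in turn. Chosen after seeing the data were the consecutive array pair as a random block, the removal of a loess trend on gene length per array, and the starvation genes within array pairs. Gene lengths come from the R64 annotation. The fit was tested on simulated data of the same layout: false calls made up 2.70% to 7.28% of calls with independent arrays and 9.64% to 17.0% with correlated array pairs, and changes of 1 log2 unit were recovered in 68.7% to 98.5% of cases with independent arrays. In the simulation few genes changed, pairs had a correlation of 0.277 and there was no length trend. These shares therefore need not hold for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

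The design has limits. The alkaline pH arrays used strain DBY4741 and 10 min of exposure, and the low glucose arrays strain DBY746 and 15 min, so treatment, strain background and time change together. The labels do not say whether arrays are independent cultures or dye swaps of the same RNA. The title of snf1 replicate 1 at alkaline pH gives the snf1 mutant, while its genotype field gives snf11::KanMX. The SNF1 spot was blank on all but 2 arrays, and a ratio within a mutant would not show a deletion, so the spot checks nothing.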

Results

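Transcript levels were measured on 12 two-colour arrays in wild type yeast and in a mutant lacking SNF1, the gene of the protein kinase that yeast needs to grow on carbon sources other than glucose. In the alkaline pH experiments, log-phase cells in 50 ml of YPD medium at 28 °C received 16 mM KOH, which brought the medium to pH 8.0, or 16 mM KCl, which left it near pH 5.5, for 10 min. In the low glucose experiments, cells were moved to 0.05% glucose or kept at 2% for 15 min. There were 4 arrays per genotype at alkaline pH (strain DBY4741) and 2 per genotype at low glucose (strain DBY746). Between 4056 and 5597 genes per array carried a value, the fewest in snf1 at low glucose. Arrays of the same group correlated across genes with Pearson coefficients of 0.683 to 0.953. Values are log2 ratios of treated over control, given as mean ± SD with n = 4 at alkaline pH and n = 2 at low glucose unless another n is stated. Folds are back-transformed, and adjusted p-values are limma's after Benjamini-Hochberg correction. For snf1 replicate 1 at alkaline pH the title names the snf1 mutant and the genotype field names snf11.

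The title of the series names a response to alkaline pH that is related to glucose starvation, and the first comparison asks what 10 min at pH 8.0 changed in wild type cells. Genes for glucose uptake, storage carbohydrates, stress defence and calcium signalling rose, and genes for making ribosomes fell. The largest rises were those of BDH2, a putative butanediol dehydrogenase (5.46 ± 0.37, 44.0-fold), RGI1, a protein of respiratory growth (5.29 ± 0.26, 39.1-fold), AIM17 (5.01 ± 0.24, 32.2-fold) and PHO89, a sodium/phosphate cotransporter (4.57 ± 0.60, 23.8-fold). They were followed by HXT2, a high-affinity glucose transporter (4.33 ± 1.37), GLC3, the glycogen branching enzyme (4.08 ± 0.44), BOP2 (4.02 ± 0.36), ENA1, the sodium pump (3.83 ± 2.18), CMK2, a calmodulin-dependent kinase (3.71 ± 0.96), and PGM2, a phosphoglucomutase (3.68 ± 0.22). The largest falls were those of JJJ3 (-3.47 ± 1.38), a chaperone partner, and of 9 genes that act in ribosome assembly or the processing and modification of ribosomal RNA. These were NOG2 (-3.35 ± 0.05, n = 3, 10.2-fold lower), SPB1 (-3.31 ± 0.54), RRP36 (-3.28 ± 0.70), ALB1 (-3.20 ± 0.30), ENP1 (-3.15 ± 0.17, 8.85-fold lower), RSA4 (-2.78 ± 0.23), UTP6 (-2.76 ± 0.54), BMT6 (-2.76 ± 1.26, n = 3) and UTP4 (-2.62 ± 0.51). In all, 2766 of 4979 tested genes were called, 1273 higher and 1493 lower, and 373 and 309 of them by at least 2-fold. The adjusted p of these named genes ran from 2.62e-10 for AIM17 to 0.0018 for ENA1.

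Hexose transporters and kinases used when glucose is low were higher in 7 of 9 measured members at pH 8.0 and lower in 1, with a median of 1.80 (camera adjusted p = 1.05e-10). Among them, the hexokinase HXK1 rose by 3.62 ± 0.15 (12.3-fold), the glucokinase GLK1 by 2.97 ± 0.38 and the high-affinity transporter HXT7 by 2.88 ± 0.18 (n = 3). HXT13 was the member that fell (-0.56). Of the 3 genes used when glucose is plentiful, HXT3 (0.77 ± 0.10, n = 3) and HXK2 (0.81 ± 0.46) rose. HXT1 was at -0.26 ± 0.17 (adjusted p = 0.106), and the list was not called (adjusted p = 0.402). Genes of sucrose and maltose use were higher in 6 of 8 members with none lower (median 0.92, adjusted p = 1.65e-07). They include the maltose activator MAL33 (3.02 ± 0.29), the invertase SUC2 (2.76 ± 0.31, 6.77-fold) and the maltose transporter MAL31 (1.88 ± 0.16). Adjusted over the list alone, 7 of these 8 were higher, and the counts of the hexose lists were the same. Genes of gluconeogenesis, the glyoxylate cycle and the use of ethanol, acetate and lactate were higher in 9 of 14 members and lower in 2 (median 0.81, adjusted p = 0.00398). This call was lost at an adjusted p = 0.455 with an estimated correlation. The members that rose include ALD4, a mitochondrial aldehyde dehydrogenase (3.03 ± 0.72), MDH2, the cytosolic malate dehydrogenase (2.35 ± 0.89), ACS1, an acetyl-CoA synthetase (2.24 ± 0.37), and the lactate transporter JEN1 (2.14 ± 0.77). FBP1, the fructose bisphosphatase of gluconeogenesis, fell (-0.64 ± 0.37).

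Genes of trehalose and glycogen metabolism were higher in 14 of 15 members at pH 8.0 with a median of 2.30 (adjusted p = 1.33e-19). GSY1, a glycogen synthase, rose by 3.59 ± 0.65, TSL1 by 3.49 ± 0.56 and TPS1 by 2.51 ± 0.24, the last 2 being subunits of trehalose synthase. General stress genes were higher in 19 of 22 members (median 1.46, adjusted p = 7.84e-15), including MSC1 (3.40 ± 0.13), TFS1 (2.97 ± 0.16) and the membrane-stabilising HSP12 (2.49 ± 0.40). Of the calcium and calcineurin response, 13 of 14 members were higher with a median of 2.74 (adjusted p = 3.25e-13), among them RCN2, a regulator of calcineurin (3.28 ± 0.27). ENA1 differed most between arrays, with values of 2.30, 1.84, 6.53 and 4.64. None of the members of these 3 lists was lower, and their counts adjusted over the list alone were the same. With an estimated correlation the calls held (adjusted p = 0.00238, 0.0014 and 0.0295).

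Ribosome biogenesis genes were lower in 67 of 71 measured members in wild type at pH 8.0 (median -1.51, adjusted p = 3.61e-34), with NOG2 and ENP1 lowest among the members, which do not include SPB1, RRP36 and ALB1, and the box C/D methyltransferase NOP1 the only member higher (1.22). Genes of RNA polymerases I and III were lower in 20 of 22 (median -0.88, adjusted p = 8.22e-07), among them RPC19 (-2.04 ± 0.39) and RPA34 (-1.63 ± 0.41). Cytosolic ribosomal protein genes were lower in 118 of 124 and higher in 3 (median -0.94, adjusted p = 3.39e-28). That call was lost at an adjusted p = 0.0904 with an estimated correlation. RPL22B was at -1.96 ± 0.23, while RPL23A (1.33 ± 0.20) and RPS11B (1.27 ± 0.42, n = 3) rose. Adjusted over the list alone, 69 of the biogenesis genes and 119 of the ribosomal protein genes were lower. The first 2 lists kept their calls with an estimated correlation (adjusted p = 0.00308 and 0.00229).

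Respiratory chain and ATP synthase genes were higher in 12 of 28 members and lower in none (median 0.08, adjusted p = 0.0336), a call lost at an adjusted p = 0.361 with an estimated correlation. The cytochrome c isoform CYC7 rose by 2.41 ± 0.44 and the NADH dehydrogenase NDI1 by 1.90 ± 0.20. Among regulators of glucose repression and induction, 7 of 20 were higher and 3 lower (adjusted p = 0.113). Rises were those of the repressor NRG1 (2.02 ± 0.11), the activator ADR1 (1.97 ± 0.28) and MIG1 (0.51 ± 0.13), while MIG2 was at -0.01 ± 0.14 (adjusted p = 0.924). The lists below were not called. In the tricarboxylic acid cycle, 5 of 14 genes were higher and 1 lower (adjusted p = 0.113), with CIT1, the citrate synthase, at 0.90 ± 0.10. Mitochondrial ribosomal protein genes were higher in 27 of 59 and lower in 4 (adjusted p = 0.064). Proteasome genes were higher in 10 of 32 and lower in 1 (adjusted p = 0.137), and oxidative stress genes higher in 5 of 13 and lower in 1 (adjusted p = 0.0616). Glycolysis genes were lower in 5 of 17 (adjusted p = 0.249). Vacuolar proton pump genes were lower in 8 of 12 and higher in 1 (adjusted p = 0.286), and ergosterol genes lower in 11 of 25 and higher in 1 (adjusted p = 0.0616).

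Of the phosphate genes, 3 of 11 were higher and 2 lower (adjusted p = 0.755), and the median (-0.06) differed in sign from the mean (0.33), PHO89 being the highest member. The secreted phosphatase PHO5 fell (-1.21 ± 0.38, n = 3), and PHO84, the high-affinity phosphate transporter, had no value on the wild type arrays at pH 8.0. Amino acid genes were higher in 6 of 36 and lower in 13 (adjusted p = 0.401). Sulfur and methionine genes were higher in 5 of 18 and lower in 6 (adjusted p = 0.804), with a median of -0.13 and a mean of 0.03. Iron genes were higher in 3 of 17 and lower in 2 (adjusted p = 0.755). Copper genes were higher in 2 of 4 and lower in 1 (adjusted p = 0.846), and cell wall genes higher in 6 of 13 and lower in 3 (adjusted p = 0.755). Fatty acid oxidation genes were higher in 3 of 9 and lower in 4 (adjusted p = 0.767). Histone genes were higher in 2 of 10 and lower in 3 (adjusted p = 0.767), and galactose genes lower in 1 of 5 (adjusted p = 0.846). Where consecutive arrays were averaged and counted as 1 replicate each, 1665 genes were called in place of 2766. ADH2 had values on 2 of the arrays (-0.16 ± 0.23) and was not tested.

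The second comparison asks what the same exposure changed in cells without Snf1. Storage carbohydrate and stress genes rose and ribosome genes fell in the mutant too. The largest rises were those of BDH2 (4.15 ± 0.43, 17.8-fold), AIM17 (3.97 ± 0.27, 15.7-fold), HSP12 (3.96 ± 0.76, 15.6-fold), RTC3 (3.34 ± 0.25, 10.1-fold) and MSC1 (3.25 ± 0.75). The largest falls were those of the ribosome factors ALB1 (-2.45 ± 0.30), NOG2 (-2.31 ± 0.19), NSR1 (-2.31 ± 0.20), RSA4 (-2.12 ± 0.48) and RRP12 (-2.08 ± 0.56). HXT7 was at -0.10 ± 0.26 (adjusted p = 0.487) and PHO89 at 0.44 ± 0.81 (adjusted p = 0.221). SUC2 rose by 0.50 ± 0.29, HXK1 by 2.35 ± 0.31 and HXT2 by 2.10 ± 0.40. Smaller rises were those of CIT1 (0.72 ± 0.20), HXK2 (0.60 ± 0.32), MIG1 (0.48 ± 0.18) and MIG2 (0.54 ± 0.16). HXT1 fell (-0.61 ± 0.34). PHO84 was called lower (-0.83 ± 0.63), but not without replicate 3 (adjusted p = 0.0672) or replicate 4 (0.0853). FBP1 (-0.60 ± 0.21, n = 3) was called lower but not without replicate 1 (0.0976) or 2 (0.0961), and MAL33 (0.36 ± 0.15) higher but not without replicate 1 (0.0791), 2 (0.107) or 4 (0.057). In all, 2203 of 4591 tested genes were called, 998 higher and 1205 lower, and 265 and 199 of them by at least 2-fold. ENA1 (3.28 and 2.71 on 2 arrays) and TPS1 (2.44 ± 0.02, n = 2) had too few values for a test, and ADH2 was at -0.23 ± 0.11 (n = 3, adjusted p = 0.101).

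In snf1 at pH 8.0, 21 of 23 general stress genes (median 1.76, adjusted p = 2.57e-20) and 10 of 12 trehalose and glycogen genes (median 1.49, adjusted p = 1.13e-12) were higher, with TPS2 at 2.71 ± 0.29 and GSY1 at 2.85 ± 0.78. The arrays stood apart in pairs: general stress medians were 1.97 and 1.93 on snf1 arrays 1 and 2 and 1.05 and 1.19 on arrays 3 and 4, and those of the 8 trehalose and glycogen genes with a value on all 8 arrays 2.72 and 2.48 against 1.78 on both. Of the calcineurin list 10 of 12 were higher (median 1.42, adjusted p = 1.09e-07), among them MEP1 (2.61 ± 0.14) and CMK2 (2.45 ± 0.34). The medians of this list ran the other way, 0.42 and 0.77 on arrays 1 and 2 against 1.88 and 1.93 on arrays 3 and 4. This call was lost at an adjusted p = 0.114 with an estimated correlation. Hexose genes used at low glucose were higher in 4 of 10 and lower in 2, with a median of 0.08 and a mean of 0.67 (adjusted p = 0.0115). That call was lost when arrays were scaled to one spread (adjusted p = 0.0803). Lower were 68 of 72 ribosome biogenesis genes (median -1.38, adjusted p = 2.29e-38), 18 of 20 genes of RNA polymerases I and III (median -0.80, adjusted p = 4.48e-07) and 115 of 122 ribosomal protein genes (median -0.88, adjusted p = 2.1e-34). The last of these calls was lost at an adjusted p = 0.0533 with an estimated correlation. For these 7 lists the counts adjusted over the list alone were the same. The other 21 lists were not called, among them gluconeogenesis (6 of 13 higher, 3 lower, adjusted p = 0.635) and sucrose and maltose use (2 of 4 higher, adjusted p = 0.739). With consecutive arrays averaged, 1246 genes were called in place of 2203.

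The third comparison tests the difference of the alkaline responses itself, snf1 minus wild type. PHO89, glucose transporters and genes for other sugars and for pyruvate and lactate transport rose less without Snf1, and a few ribosome assembly genes fell less. PHO89 differed most (-4.13 ± 0.40 SE, 17.6-fold, adjusted p = 0.000422), followed by HXT7 (-3.01 ± 0.17), the condensin subunit YCS4 (-2.83 ± 0.39), MAL33 (-2.66 ± 0.16), SUC2 (-2.26 ± 0.18), BOP2 (-2.20 ± 0.19), the glucose transporter HXT4 (-2.14 ± 0.20), JEN1 (-2.09 ± 0.29) and MPC3, a mitochondrial pyruvate carrier (-1.82 ± 0.18). Their means in wild type and snf1 were 2.88 and -0.10 for HXT7, 3.13 and 0.29 for YCS4, 2.14 and 0.05 for JEN1, and 3.10 and 1.29 for MPC3. HXK1 rose in both genotypes and by less in snf1 (-1.27 ± 0.17, adjusted p = 0.00282), a call lost when arrays were scaled to one spread (-0.97, adjusted p = 0.139). EXG1, an exoglucanase of the cell wall (1.36 ± 0.18, adjusted p = 0.00282), and ENP1 (1.35 ± 0.17, adjusted p = 0.00174) were higher in snf1, where they fell by less (EXG1 -0.73 ± 0.20 against -2.09 ± 0.36). HXT2 (-2.23 ± 0.52, adjusted p = 0.0646), HSP12 (1.47 ± 0.42, adjusted p = 0.101), MIG2 (0.55, adjusted p = 0.0579), HXT1 (-0.35, adjusted p = 0.387), HXK2 (-0.21, adjusted p = 0.753), CIT1 (-0.19, adjusted p = 0.594), MIG1 (-0.03, adjusted p = 0.955) and FBP1 (0.07, adjusted p = 0.944) were not called.

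In all, 51 of 4380 genes differed between genotypes at pH 8.0, 18 higher and 33 lower in snf1. Lower were also PUN1 (-1.65 ± 0.29), ALD4 (-1.61 ± 0.29), GDB1, the glycogen debranching enzyme (-1.16 ± 0.19), HXT3 (-1.08 ± 0.16) and USV1 (-0.59 ± 0.12). Higher were SPB1 (1.36 ± 0.23), NOG2 (1.04 ± 0.17), PPR1, ROG3, PUS1, RPS27B, CDC6, UTP18 and SUL2, the last 7 by 0.77 to 1.19. Without wild type replicate 4 these genes other than NOG2 lost their calls, with adjusted p between 0.0594 for HXT3 and 0.145 for CDC6 and USV1. Of these 13 genes, 10 (all but HXT3, GDB1 and SPB1) lost their calls without snf1 replicate 2 too (0.0539 to 0.0927). PUN1, ALD4, CDC6, ROG3, PUS1, SUL2 and USV1 did so without snf1 replicate 1 (0.0636 to 0.125), and PPR1, PUS1, ROG3, SUL2, USV1 and UTP18 without snf1 replicate 4 (0.0569 to 0.0604). ALD4, CDC6, PPR1, PUS1, ROG3, SUL2, USV1, UTP18 and NOG2 did so without wild type replicate 3 (0.0605 to 0.173), and PUS1, ROG3, RPS27B, SUL2, USV1, UTP18 and NOG2 without replicate 2 (0.0643 to 0.119). UTP18 did so without replicate 1 (0.0675). When arrays were scaled, PUN1, ALD4, USV1, SPB1, NOG2, PPR1, PUS1, RPS27B, CDC6 and UTP18 lost their calls (0.052 to 0.232), and HSP12 (2.10, adjusted p = 0.00908) and MIG2 (0.69, adjusted p = 0.0432) gained one. The number of genes called was 90, 28 or 22 without wild type replicate 1, 3 or 4, and 161 without snf1 replicate 3. It was 23 with the consecutive array pair as a random block, 2 higher and 21 lower, and 0 of 3723 with consecutive arrays averaged, by limma, where 257 genes had an unadjusted p under 0.05.

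**Figure D1:**
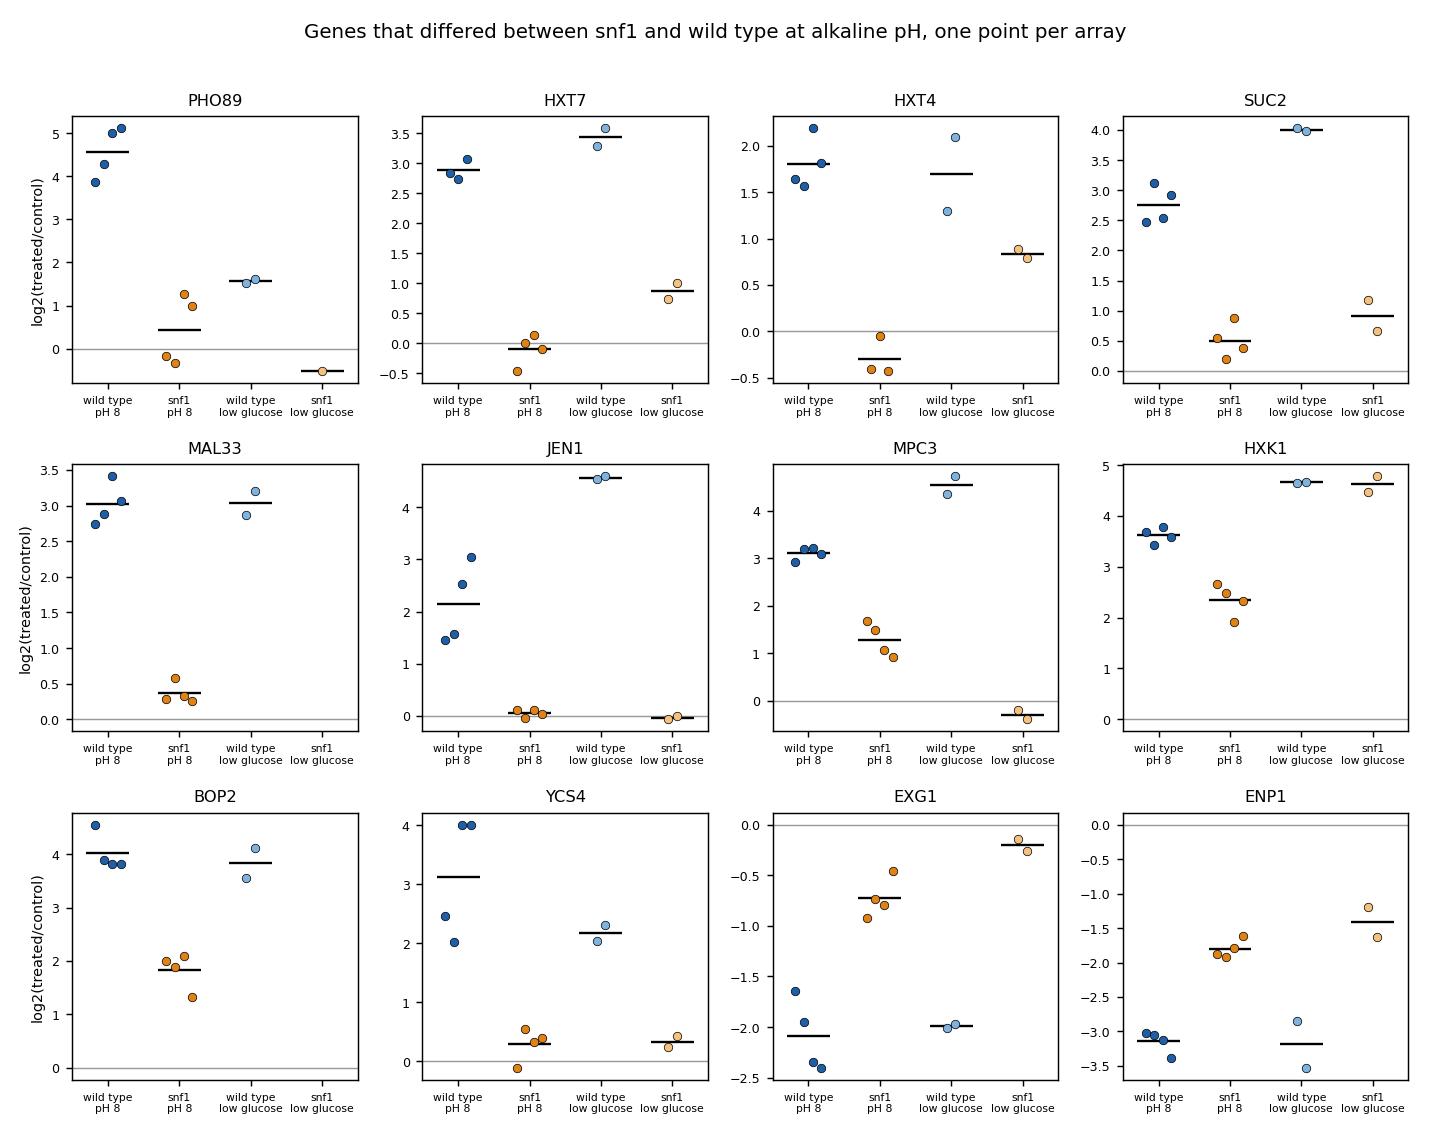
Log2 ratios of treated over control for 12 genes that differed between genotypes, 1 point per array and a line at each group mean, in wild type and snf1 at pH 8.0 and at low glucose. At pH 8.0 the HXT7 means were 2.88 in wild type and -0.10 in snf1, and at low glucose the SUC2 means were 4.00 and 0.92. HXK1 was not called different between genotypes at low glucose, but was called higher in snf1 there when arrays were scaled. The scale factors turn a gene raised alike in both genotypes in that direction.

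Among the fixed lists, 7 of 28 differed between genotypes at pH 8.0. Hexose genes used at low glucose were lower in snf1 (median -1.10, adjusted p = 6.15e-18), with 3 of 9 called and 6 of 9 when adjusted over the list alone. Sucrose and maltose genes were lower (median -1.60, adjusted p = 2.19e-24), 2 of 4 called and 4 of 4 over the list alone, with MAL32 at -0.93. For this list and that of transport at high glucose no correlation could be estimated. Their p-values rest on the preset correlation of 0.01 and take the arrays as independent. Members of a list with near-identical sequence may share signal on spotted probes, so counts of members need not be counts of independent genes. The calcineurin list was lower (median -0.80, adjusted p = 3.91e-09), with PHO89 called of 12 members and 7 over the list alone, among them ENA2, RCN2 and CMK2 at -1.79, -1.02 and -1.26 (list median -0.52 with arrays scaled). On arrays 1 to 4 the medians of this list were 0.42, 0.77, 1.88 and 1.93 in snf1 and 2.15, 2.38, 2.995 and 3.15 in wild type. That call was lost at an adjusted p = 0.213 with an estimated correlation. Gluconeogenesis genes (median -0.47, adjusted p = 0.000657) had JEN1 and ALD4 called of 11, 5 lower and 1 higher over the list alone, and an adjusted p = 0.468 with an estimated correlation. Trehalose and glycogen genes (median -0.40, adjusted p = 0.0058) had GDB1 called of 12, 3 over the list alone, an adjusted p = 0.85 with an estimated correlation and 0.241 after scaling (median -0.18). Over the 8 members with a value on all 8 arrays, medians on arrays 1 to 4 were 2.38, 2.46, 2.97 and 2.795 in wild type. In snf1 they were 2.72, 2.48, 1.78 and 1.78, so within arrays 1 and 2 snf1 was not lower. The list of transport at high glucose was lower (median -0.35, adjusted p = 0.0058), with HXT3 called of 3. Ribosome biogenesis genes were shifted up (median 0.09, adjusted p = 0.0058), but the median turned to -0.12 when arrays were scaled (adjusted p = 0.814). NOG2, ENP1 and UTP18 were called of 69, and the list had an adjusted p = 0.892 with an estimated correlation. General stress genes were not called (median -0.08 and mean 0.05, adjusted p = 0.469), and their median turned to 0.23 when arrays were scaled.

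**Figure D2:**
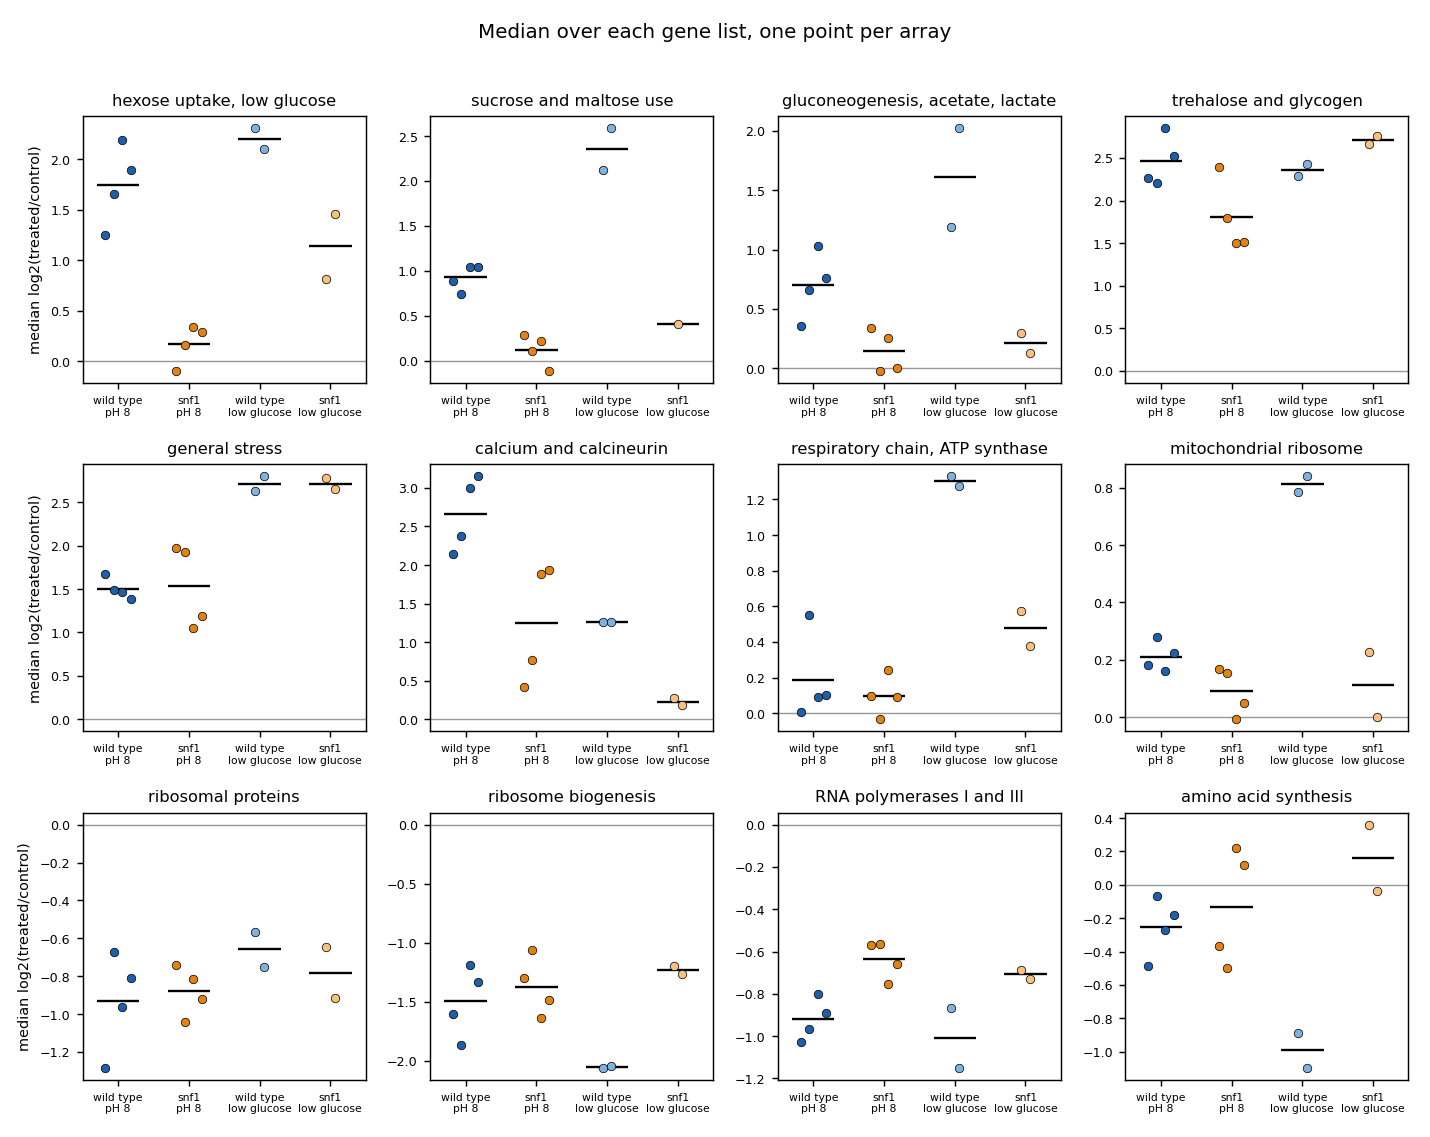
Median log2 ratio per array of 12 gene lists in the 4 groups, 1 point per array and a line at the mean of each group. Each median is over the members with a value on that array, and arrays with fewer than 3 such members are not shown. For sucrose and maltose use in snf1 at low glucose this leaves array 2 alone, with 3 members. At pH 8.0 the medians of the hexose genes used at low glucose lay between 1.24 and 2.19 on the wild type arrays and between -0.10 and 0.33 on the snf1 arrays. Over the 4 members with a value on all 8 arrays they lay between 2.94 and 3.36 in wild type and between 1.95 and 2.41 in snf1, so these members rose in both genotypes.

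The fourth comparison gives the response of wild type cells to 15 min of low glucose, the starvation response to which the alkaline response is related in the title of the series. Genes for respiration, hexose uptake, sucrose and maltose use and stress defence rose, and genes for making ribosomes fell. The amino acid and ergosterol lists were lower too, calls lost at an adjusted p = 0.386 and 0.302 with an estimated correlation. The largest rises were those of RGI1 (128-fold, SD 0.67 on the log2 scale), BDH2 (5.86 ± 0.13, 58.3-fold), AIM17 (5.80 ± 0.20, 55.9-fold), ISF1 (5.23 ± 0.41), the peroxisomal citrate synthase CIT2 (4.93 ± 0.09), GSY1 (4.85 ± 0.28), PGM2 (4.73 ± 0.08), the carbonic anhydrase NCE103 (4.67 ± 0.00), HXK1 (4.66 ± 0.01) and JEN1 (4.56 ± 0.04, 23.6-fold). The largest falls were those of RRP12 (-4.38 ± 0.28, 20.8-fold lower), SPB1 (-4.30 ± 0.16), the RNA-binding protein SRO9 (-4.13 ± 0.39), the fatty acid synthase FAS1 (-4.10 ± 0.16), the drug resistance regulator PDR3 (-4.01 ± 0.65), the pyrimidine enzyme URA2 (-3.99 ± 0.27), NEW1 (-3.83 ± 0.19), the ribonucleotide reductase RNR1 (-3.83 ± 0.19), the glucan synthase FKS1 (-3.79 ± 0.25) and NSR1 (-3.78 ± 0.17). Of 5225 tested genes 3405 were called, 1759 higher and 1646 lower, and 795 and 871 of them by at least 2-fold.

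Ratios in this group fell with gene length. The median was 0.55 for 491 genes under 500 bp and -1.71 for 146 genes of 4000 bp or more, and the Spearman correlation with length across genes was -0.448 and -0.409 on the 2 arrays, against -0.085 and -0.019 in snf1 at low glucose. FAS1, URA2, FKS1 and RGI1, named above, kept their direction with this trend removed. Scaling to one spread multiplies these arrays by 0.640 and 0.624, which brings the medians below nearer to 0. With arrays so scaled 2123 genes were called in place of 3405, and the list calls below held.

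**Figure D3:**
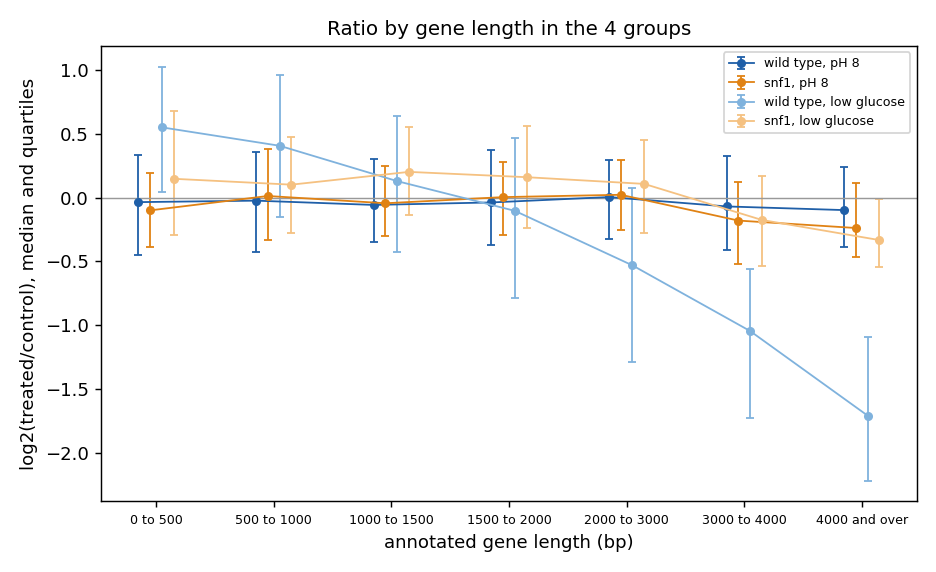
Median log2 ratio (points) and quartiles (bars) of genes binned by annotated length in bp, in the 4 groups. Medians fell from 0.55 to -1.71 in wild type at low glucose and stayed between -0.33 and 0.20 in snf1 at low glucose.

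In wild type at low glucose, 21 of 22 general stress genes were higher (median 2.76, adjusted p = 1.18e-14), among them HSP12 (4.38 ± 0.44) and TFS1 (4.35 ± 0.02). So were 14 of 15 trehalose and glycogen genes (median 2.45, adjusted p = 3.21e-07), among them TPS1 (2.45 ± 0.03). The latter call was lost at an adjusted p = 0.133 with an estimated correlation. Sucrose and maltose genes were higher in 7 of 8 (median 2.39, adjusted p = 1.35e-07), with SUC2 at 4.00 ± 0.04 (16.0-fold) and MAL33 at 3.04 ± 0.24. Hexose genes used at low glucose were higher in 7 of 9 (median 2.33, adjusted p = 2.44e-06), with HXT7 at 3.44 ± 0.21 and HXT6 at 3.27 ± 0.11. HXT1, the low-affinity transporter, fell (-1.70 ± 0.49). HXT2 rose by 2.33 ± 0.03, a call lost when arrays were scaled (1.43, adjusted p = 0.0605). Gluconeogenesis genes were higher in 13 of 15 (median 1.47, adjusted p = 0.000106), with ADY2, an acetate transporter, at 3.03 ± 0.05 and MLS1, the malate synthase, at 2.88 ± 0.33. This list had an adjusted p = 0.273 with an estimated correlation. FBP1 (0.51 ± 0.23) and MIG2 (0.38 ± 0.24) were called but not without replicate 1 (adjusted p = 0.33 and 0.216) or replicate 2 (0.142 and 0.0816). PHO89 (1.57 ± 0.07) was not called without replicate 2 (0.084), and these 3 genes were not called when arrays were scaled. MIG1 rose by 1.27 ± 0.12, and HXK2 was at 0.14 ± 0.33 (adjusted p = 0.584). The copper list was higher in 6 of 6 (median 0.94, adjusted p = 0.0133), with the copper transporter CTR1 at 2.33 ± 0.18. The copper list had an adjusted p = 0.15 with an estimated correlation. With the length trend removed, the hexose, stress, sucrose and trehalose lists had 7, 21, 8 and 15 members higher, gluconeogenesis 12 and copper 5.

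Respiratory genes rose with low glucose in wild type, and these lists moved with the length trend. Oxidative phosphorylation genes were higher in 23 of 28 and lower in 3 (median 1.37, adjusted p = 3.58e-07), with CYC7 at 4.01 ± 0.47, NDI1 at 2.96 ± 0.09 and QCR8 at 2.26 ± 0.02. With the trend removed 20 were higher and 1 lower (median 0.81, adjusted p = 0.000202). Mitochondrial ribosomal protein genes were higher in 50 of 60 and lower in 2 (median 0.80, adjusted p = 2.06e-06), with RSM10 at 2.19 ± 0.09. They had an adjusted p = 0.0525 with an estimated correlation, and 33 were higher and 3 lower with the trend removed (median 0.39). Tricarboxylic acid cycle genes were higher in 10 of 14 and lower in 2 (median 0.67, adjusted p = 0.0211), with SDH2 at 2.17 ± 0.33 and CIT1 at 1.67 ± 0.10. The list had an adjusted p = 0.397 with an estimated correlation, and 8 were higher with the trend removed. Oxidative stress genes were higher in 6 of 13 (median 0.34, adjusted p = 0.0211), with TSA2 at 2.50 ± 0.08. The call was lost at an adjusted p = 0.386 with an estimated correlation, and 5 were higher and 3 lower with the trend removed (adjusted p = 0.092). Histone genes, which are short, were higher in 8 of 10 (median 0.82, adjusted p = 0.0275), with HTB2 at 1.32 ± 0.05. They had an adjusted p = 0.377 with an estimated correlation, and 3 were higher with the trend removed (adjusted p = 0.497).

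Growth-related lists fell at low glucose in wild type. Ribosome biogenesis genes were lower in 67 of 72 (median -2.03, adjusted p = 8.09e-25) and genes of RNA polymerases I and III in 20 of 21 (median -1.23, adjusted p = 4.26e-05), with RPA135 at -3.11 ± 0.05 and RPO31 at -3.10 ± 0.23. Ribosomal protein genes were lower in 85 of 124 and higher in 5 (median -0.68, adjusted p = 9.28e-06), with RPS0B at -1.75 ± 0.02. They had an adjusted p = 0.49 with an estimated correlation, and 117 were lower and 3 higher with the length trend removed (median -1.03). Amino acid genes were lower in 24 of 36 (median -0.95, adjusted p = 4.84e-05), with ILV5 at -3.00 ± 0.03 and ARO1 at -2.74 ± 0.21. Ergosterol genes were lower in 18 of 25 (median -0.73, adjusted p = 0.000562), with the reductase HMG1 at -2.48 ± 0.14 and ERG1 at -1.95 ± 0.04. Vacuolar proton pump genes were lower in 8 of 12 (median -0.61, adjusted p = 0.0264), with VMA1 at -2.27 ± 0.08. With an estimated correlation these 3 calls were lost, at an adjusted p = 0.386, 0.302 and 0.386, and with the length trend removed 25, 19 and 9 members were lower. Adjusted over the list alone, 86 ribosomal protein genes were lower, 1 gene of the polymerases was higher and 9 histone genes were higher, and the other called lists had the same counts. The other 11 lists were not called, among them the calcineurin list (8 of 13 higher, 4 lower, adjusted p = 0.316).

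The fifth comparison gives the response to low glucose without Snf1. General stress, storage carbohydrate and phosphate genes rose, and genes for making ribosomes fell. The largest rises were those of the membrane heat shock protein HSP30 (5.59 ± 0.07, 48.1-fold), PGM2 (4.88 ± 0.03, 29.4-fold), HXK1 (4.63 ± 0.22, 24.7-fold), BDH2 (4.23 ± 0.38) and the mitochondrial chaperone HSP78 (4.15 ± 0.00). The largest falls were those of NSR1 (-2.64 ± 0.18), RRP12 (-2.58 ± 0.12), SPB1 (-2.53 ± 0.02), SRO9 (-2.44 ± 0.34) and SSF1 (-2.26 ± 0.04). PHO84 rose by 3.66 ± 0.47 (12.6-fold), TPS1 by 2.83 ± 0.10, CIT1 by 1.81 ± 0.15 and HXT7 by 0.87 ± 0.19. HXT1 fell (-1.85 ± 0.15), and HXT2 was at -0.23 ± 0.17 (adjusted p = 0.745). Calls that ended without replicate 1 were those of HSP12 (2.19 ± 1.23, adjusted p = 0.116) and SUC2 (0.92 ± 0.36, 0.0743). Those that ended without either replicate were HXK2 (0.84 ± 0.21, 0.121 and 0.0911), MIG1 (0.45 ± 0.11, 0.0753 and 0.246) and MIG2 (-0.46 ± 0.18, 0.0927 and 0.109). Of 3703 tested genes 1696 were called, 1070 higher and 626 lower, and 318 and 177 of them by at least 2-fold. Without either replicate, or with the 2 arrays averaged, fewer genes were called. Each of these leaves 1 value per gene in this group, so such calls rest on the spread of other groups.

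In snf1 at low glucose, 22 of 22 general stress genes (median 2.66, adjusted p = 6.64e-25) and 13 of 13 trehalose and glycogen genes (median 2.77, adjusted p = 1.48e-17) were higher, with the chaperones HSP26 at 4.03 and SSA4 at 4.00. Hexose genes used at low glucose were higher in 5 of 6 (median 1.51, adjusted p = 9.34e-08), with HXT6 at 2.14 and GLK1 at 2.98. Higher were also 7 of 10 phosphate genes (median 0.60, adjusted p = 0.0324), and 6 of 10 cell wall genes, with 1 lower (median 0.60, adjusted p = 0.00101), with PIR3 at 2.66 and PST1 at 2.60. The calls of the stress, trehalose and cell wall lists held with an estimated correlation. Oxidative phosphorylation genes (12 of 22 higher, median 0.49, adjusted p = 0.0206), tricarboxylic acid cycle genes (9 of 14, median 0.65, adjusted p = 0.0183), oxidative stress genes (9 of 13, median 0.52, adjusted p = 0.00638) and copper genes (3 of 5, median 0.65, adjusted p = 0.0403) were higher. These 4 calls were lost at an adjusted p = 0.218, 0.446, 0.25 and 0.203 with an estimated correlation. Lower were 63 of 69 ribosome biogenesis genes (median -1.21, adjusted p = 1.15e-27), 13 of 17 genes of the polymerases (median -0.74, adjusted p = 1.49e-05) and 95 of 116 ribosomal protein genes (median -0.81, adjusted p = 8.4e-24). The last of these had an adjusted p = 0.118 with an estimated correlation. Adjusted over the list alone, 64, 14 and 97 of these were lower and 13 oxidative phosphorylation genes higher, the other called lists being the same. The other 15 of 27 lists were not called, among them gluconeogenesis (1 of 8 higher, 1 lower, adjusted p = 0.678). The list of sucrose and maltose use had fewer than 3 members with a value on both arrays and was not tested.

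The sixth comparison tests the difference of the low glucose responses, snf1 minus wild type. MPC3, JEN1, SUC2, HXT7 and genes of mitochondrial ribosomal proteins were lower without Snf1, and DED1, URA2, FAS1 and GCN1 were higher. The amino acid and ergosterol lists were higher too, calls lost at an adjusted p = 0.358 for both with an estimated correlation. The lowest in snf1 were MPC3 (-4.84 ± 0.26 SE, adjusted p = 1.9e-06), JEN1 (-4.60 ± 0.42), the proline oxidase PUT1 (-3.74 ± 0.33) and SUC2 (-3.08 ± 0.26, adjusted p = 2.11e-05). Their wild type and snf1 means were 4.54 and -0.30, 4.56 and -0.03, 4.16 and 0.42, and 4.00 and 0.92. HXT7 was lower by -2.57 ± 0.22, CYC7 by -2.96 and RSM10 by -1.90. HXT6, which is near-identical in sequence to HXT7 and may share its signal, was lower by less (-1.13). The highest were the splicing factor PRP6 (3.79 ± 0.80, adjusted p = 0.00301), the RNA helicase DED1 (3.56 ± 0.28), URA2 (3.49 ± 0.31), FAS1 (3.37 ± 0.21) and the translation regulator GCN1 (3.27 ± 0.22). Their snf1 means were 3.20, 0.48, -0.50, -0.73 and -0.42 against -0.58, -3.08, -3.99, -4.10 and -3.69 in wild type. The difference rose with gene length (Spearman correlation 0.547 across genes). With the length trend removed PRP6, DED1, URA2, FAS1 and GCN1 were at 3.02, 3.21, 1.94, 1.87 and 1.56 and kept their calls. HSP104 (2.06), YGP1 (2.00), TPS2 (1.78) and TPS3 (1.59) were higher in snf1, and at 1.28, 2.04, 1.02 and 0.69 with the trend removed. RGI1 (-3.31 ± 0.84), HSP12 (-2.19 ± 0.59), HXT2 (-2.56 ± 0.74), HXT4 (-0.86), TMA10 (-2.74), ALD4 (-2.14) and MIG1 (-0.82) were called lower, but not when arrays were scaled (adjusted p from 0.0535 for ALD4 to 0.669 for RGI1). MIG2 was lower by -0.84 ± 0.17. HXT6 (-1.13) and GSY1 (-1.59) were called lower but turned to 0.08 and 0.26 when arrays were scaled. Scaling multiplies the wild type arrays at low glucose by 0.640 and 0.624 and the snf1 arrays by 0.905 and 1.16. A gene raised alike in both genotypes is thereby turned higher in snf1, and one lowered alike is turned lower. Calls gained or lost by scaling in this difference therefore depend on these factors.

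HXK1 (-0.03, adjusted p = 0.923), TPS1 (0.38, adjusted p = 0.145), CIT1 (0.14, adjusted p = 0.61), HXK2 (0.69, adjusted p = 0.0954) and HXT1 (-0.15, adjusted p = 0.665) were not called in this difference. When arrays were scaled, HXK1 (1.81, adjusted p = 0.0166) and TPS1 (1.33, adjusted p = 0.0124) were called higher in snf1, the direction in which the scale factors turn genes raised alike in both genotypes. Without wild type replicate 2, the calls of RGI1 (adjusted p = 0.0726), HSP12 (0.122), HXT2 (0.0832), HXT4 (0.246), HXT6 (0.0514), MIG1 (0.066) and GSY1 (0.227) ended. Without snf1 replicate 1 those of RGI1 (0.0567), HXT2 (0.073), MIG1 (0.0608) and GSY1 (0.153) ended. Without snf1 replicate 2 those of HSP12 (0.152), HXT2 (0.0868), HXT4 (0.172), HXT6 (0.0628) and GSY1 (0.0841) ended. Without wild type replicate 1, HXT2 lost its call as well (0.0737). In all, 1481 of 3651 genes were called, 1007 higher and 474 lower in snf1. With 1 array left out, or the arrays of a group averaged, fewer genes were called. A group then keeps 1 value per gene, and such calls rest on the spread of other groups. The count was 467 with arrays scaled to one spread. With the length trend removed it was 1179, 710 higher and 469 lower, and 912 of these were among the 1481.

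Of 27 lists, 11 differed between genotypes at low glucose. The list of sucrose and maltose use was not tested, since fewer than 3 members had values on the snf1 arrays compared. Spots under 100 units were left out, so genes weak in snf1 may be missing from this difference. Of the gluconeogenesis list 7 members were tested, against 15 in wild type alone. Hexose genes used at low glucose were lower in snf1 (4 of 6 lower, median -0.99, adjusted p = 0.0111), a call lost when arrays were scaled (median -0.08, adjusted p = 0.757). Mitochondrial ribosomal protein genes were lower (20 of 34, median -0.64, adjusted p = 1.22e-07), 11 of them with the length trend removed and 3 with arrays scaled (median -0.43). Oxidative phosphorylation genes were lower (10 of 21 lower and 2 higher, median -0.58, adjusted p = 0.000256), 5 of them with the trend removed and 4 with arrays scaled (median -0.17). QCR9 was at -2.13 and QCR8 at -1.51. With an estimated correlation the mitochondrial list had an adjusted p = 0.0202 and that of oxidative phosphorylation 0.0549. Gluconeogenesis genes (4 of 7 lower, median -0.66, adjusted p = 0.0036; 2 lower and median -0.37 with arrays scaled) had an adjusted p = 0.299 with an estimated correlation, and SDH2 of the tricarboxylic acid cycle was at -2.07. Histone genes (3 of 10 lower, median -0.21, adjusted p = 0.0305), with HTB2 at -1.39 and HHF2 at -1.27 (not called with arrays scaled, adjusted p = 0.0562), had an adjusted p = 0.37 with an estimated correlation, 0.737 with the trend removed, where the median turned to 0.18, and 0.109 after scaling. Ribosomal protein genes (3 of 116 higher and 9 lower, median -0.07, adjusted p = 0.0275) had an adjusted p = 0.821 with an estimated correlation, and 15 higher and 2 lower with a median of 0.20 with the trend removed. Scaled, their median was -0.39, with 6 lower.

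Higher in snf1 than in wild type at low glucose were amino acid genes (26 of 34, median 1.39, adjusted p = 2.71e-07), with the aspartate kinase HOM3 (3.10) and ARO1 (2.71), and ergosterol genes (16 of 22, median 0.91, adjusted p = 0.00325), with HMG2 (1.60) and HMG1 (1.47). So were vacuolar proton pump genes (6 of 9, median 0.70, adjusted p = 0.00517), with VMA1 (2.29) and VPH1 (2.08), and cell wall genes (7 of 10 higher and 1 lower, median 0.77, adjusted p = 0.039). With an estimated correlation these calls were lost, at an adjusted p = 0.358, 0.358, 0.299 and 0.299, and with the length trend removed 24, 11, 6 and 7 members were higher. With arrays scaled 7 amino acid genes (median 0.72), 3 ergosterol genes (median 0.40), 3 vacuolar pump genes and 5 cell wall genes were higher. HMG1 and HMG2 were not called when arrays were scaled. Ribosome biogenesis genes were higher in 32 of 68 (median 0.79, adjusted p = 0.00125), but the median turned to -0.04 when arrays were scaled (adjusted p = 0.247). UTP22 was at 2.15, and the list had an adjusted p = 0.627 with an estimated correlation. The polymerase subunit RPA135 (2.05) and UTP22 were not called when arrays were scaled. The glycolytic PFK1 (2.45) and PFK2 (2.22) were higher in a list that was not called (4 of 16 higher, median -0.03 and mean 0.38, adjusted p = 0.465). Trehalose and glycogen genes (3 of 13 higher, 2 lower, median 0.20 and mean -0.01, adjusted p = 0.971) and general stress genes (3 of 22 higher, 8 lower, median -0.22, adjusted p = 0.0937) were not called. When arrays were scaled they were higher in snf1, with medians of 1.27 and 0.97 (adjusted p = 0.000832 and 0.00678). The scale factors turn lists raised alike in both genotypes in this direction, so these calls by themselves show no difference between genotypes. Adjusted over the list alone, 30 amino acid genes, 35 biogenesis genes and 7 vacuolar pump genes were higher and 22 mitochondrial ribosomal genes lower. By the same count 1 ribosomal protein gene was higher and 3 lower, the other called lists having the same counts.

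The seventh comparison asks how far the alkaline and starvation responses of wild type cells coincide. BDH2, RGI1, AIM17, GSY1, PGM2, HXK1, SUC2 and HSP12 rose in both, and SPB1, RRP12 and NSR1 fell in both. Of 4825 genes tested in both, 925 were called higher in both, 74.2% of the 1247 called higher at pH 8.0, against 427 in independent lists (Fisher exact p = 2.86e-255). Lower in both were 903, against 450.1 (Fisher exact p = 1.91e-200). Opposite directions were rarer: 79 genes rose at pH 8.0 and fell at low glucose (389 in independent lists), and 55 did the reverse (493). Among the first were GSC2, PMC1 and PMR1 of the calcineurin list, which rose at pH 8.0 (1.90, 1.18 and 0.56) and fell at low glucose (-1.99, -1.23 and -1.69). GSC2 was not called at low glucose without replicate 2 (adjusted p = 0.067) or with the length trend removed (-0.20, adjusted p = 0.676). In wild type, mean log2 ratios correlated across genes with Pearson r = 0.714 and Spearman rho = 0.671, and 0.798 and 0.756 with the length trend removed. Those of snf1 at pH 8.0 and at low glucose correlated too, over 3290 genes. Pearson r was 0.7499 and Spearman rho 0.6885, and 0.7533 and 0.6935 with the length trend removed (3136 genes). The correlation between the stresses was therefore not confined to wild type. Genes are not independent replicates, so these values describe the genes measured. With consecutive arrays averaged, fewer genes were higher in both stresses in wild type. Averaging leaves 1 value per gene at low glucose, so the calls there rest on the spread of the pH 8.0 arrays.

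**Figure D4:**
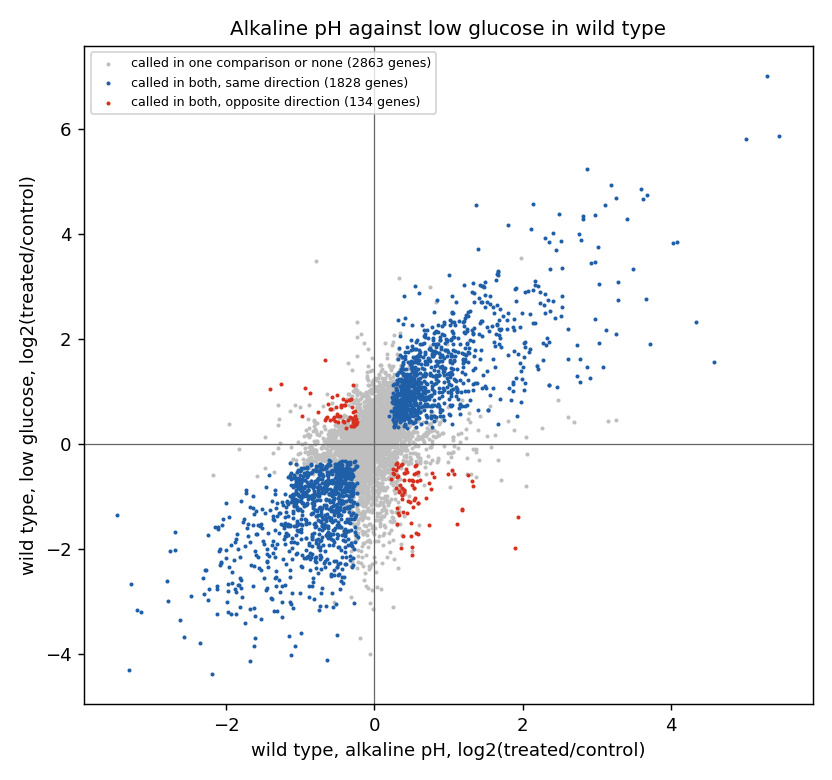
Mean log2 ratio of each of 4825 genes in wild type at pH 8.0 (horizontal axis) against low glucose (vertical axis), coloured by call. The 1828 genes called in both in the same direction outnumber the 134 called in opposite directions.

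The last comparison asks whether the starvation genes respond to alkaline pH with and without Snf1. The genes were chosen on the wild type low glucose arrays alone. The 795 genes raised at least 2-fold there had a median at pH 8.0 of 0.75 ± 0.06 (SD of 4 arrays) in wild type and 0.64 ± 0.10 in snf1. The difference of -0.12 did not pass an exact two-sided permutation test (p = 0.143, smallest possible 0.0286 over 70 assignments). Within arrays 1 and 2 of each genotype the difference was -0.03, and within arrays 3 and 4 it was -0.20. With the length trend removed, which leaves 593 genes raised at least 2-fold, it was -0.18 (exact p = 0.0286, the smallest possible). Without that removal, as a mean over the 795 genes, it was -0.20 (exact p = 0.0571). For 798 raised genes chosen in a fit of the wild type low glucose arrays alone, the difference of medians was -0.117 (exact permutation p = 0.143). These tests treat the 4 arrays as independent, and with consecutive arrays averaged the difference was -0.12 (exact p = 0.333, the smallest that 2 against 2 can give). The 871 genes lowered at least 2-fold had medians of -0.57 ± 0.10 in wild type and -0.53 ± 0.09 in snf1 (difference 0.04, exact permutation p = 0.6), and that difference turned to -0.02 when arrays were scaled.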

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

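The tests of the gene length trend, of the overall strength of the snf1 arrays at pH 8.0, of the random pair block, of the splits that keep array pairs whole, of SUC2 and HXT7 on snf1 array 1, of medians over genes with a value on all 8 arrays and of the 256 genes lower in snf1 at low glucose were chosen after the results were seen, as was the removal of the length trend. The test of a strain that kept SNF1 and the counts over other splits of the arrays were planned.

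At pH 8.0, 51 genes differed between snf1 and wild type by the test of the difference itself. Of the 35 ways to split the 8 arrays into 4 and 4, 1 called as many genes, the real one, and the highest other split called 21. These splits treat the arrays as independent, while consecutive arrays deviated together (residual correlations 0.16, 0.50, 0.68 and 0.25). Of the 3 splits that keep consecutive arrays whole, 1 called as many genes, the others 21 and 16, and 3 splits are too few for a share under 0.05. The count was 90 without wild type replicate 1, 28 without replicate 3, 22 without replicate 4 and 161 without snf1 replicate 3. Within each genotype at pH 8.0, exchanging the channels gives 8 patterns, too few for a share under 0.05. In wild type 1 pattern called as many as 2766 genes and the highest other 6, and in snf1 1 called as many as 2203 and the highest other 11.

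Lower in snf1 than in wild type at pH 8.0 by that test were PHO89 (-4.13), HXT7 (-3.01), YCS4 (-2.83), MAL33 (-2.66), SUC2 (-2.26), BOP2 (-2.20), HXT4 (-2.14), JEN1 (-2.09), MPC3 (-1.82), PUN1 (-1.65), ALD4 (-1.61), HXK1 (-1.27), GDB1 (-1.16), HXT3 (-1.085) and USV1 (-0.59). Higher were EXG1 (1.36), SPB1 (1.36), ENP1 (1.35), PPR1 (1.19), ROG3 (1.12), PUS1 (1.11), NOG2 (1.04), RPS27B (1.04), CDC6 (1.02), UTP18 (0.88) and SUL2 (0.77). Without wild type replicate 4, adjusted p rose to between 0.0594 and 0.145 for PUN1, ALD4, HXT3, GDB1, USV1, SPB1, PPR1, ROG3, PUS1, RPS27B, CDC6, UTP18 and SUL2. All of these but HXT3, GDB1 and SPB1 also lost their calls without snf1 replicate 2 (0.0539 to 0.0927). Some did so without snf1 replicates 1 (0.0636 to 0.125) or 4 (0.0569 to 0.0604), and, with NOG2, without wild type replicates 2 (0.0643 to 0.119) or 3 (0.0605 to 0.173). UTP18 did so without wild type replicate 1 (0.0675). When arrays were scaled, PUN1, ALD4, HXK1, USV1, SPB1, NOG2, PPR1, PUS1, RPS27B, CDC6 and UTP18 lost theirs (0.052 to 0.232).

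At low glucose 1481 genes differed between genotypes by the same test, 962 without wild type replicate 2. Lower in snf1 were MPC3 (-4.84), JEN1 (-4.60), PUT1 (-3.74), RGI1 (-3.31), SUC2 (-3.08), CYC7 (-2.955), TMA10 (-2.74), HXT7 (-2.57), HXT2 (-2.5555), HSP12 (-2.19), ALD4 (-2.14), QCR9 (-2.13), SDH2 (-2.07), RSM10 (-1.90), QCR8 (-1.51), HTB2 (-1.39), HHF2 (-1.27), HXT4 (-0.8575), MIG2 (-0.84) and MIG1 (-0.82). HXT6 (-1.1295) and GSY1 (-1.59) were lower too but turned to 0.08 and 0.26 when arrays were scaled. Without wild type replicate 2, RGI1, HXT2, HSP12, HXT4, HXT6, MIG1 and GSY1 lost their calls (adjusted p 0.0514 to 0.246). RGI1, HXT2, MIG1 and GSY1 also did so without snf1 replicate 1 (0.0567 to 0.153), HSP12, HXT2, HXT4, HXT6 and GSY1 without snf1 replicate 2 (0.0628 to 0.172), and HXT2 without wild type replicate 1 (0.0737). Higher in snf1 were PRP6 (3.7855), DED1 (3.5595), URA2 (3.49), FAS1 (3.37), GCN1 (3.27), HOM3 (3.10), ARO1 (2.71), PFK1 (2.45), VMA1 (2.29), PFK2 (2.22), UTP22 (2.15), VPH1 (2.08), HSP104 (2.06), RPA135 (2.05), YGP1 (2.00), TPS2 (1.78), HMG2 (1.60), TPS3 (1.59) and HMG1 (1.47). With the length trend removed PRP6, DED1, URA2, FAS1 and GCN1 were at 3.02, 3.21, 1.94, 1.87 and 1.56, and HMG2 lost its call (0.0775). When arrays were scaled, RGI1, HSP12, HXT2, HXT4, TMA10, ALD4, MIG1, HHF2, HMG1, HMG2, UTP22 and RPA135 lost theirs (0.0535 to 0.669).

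Ratios in wild type at low glucose fell with gene length, while the correlations in snf1 were -0.085 and -0.019. A dye effect is argued against by correlations with length of -0.448 and -0.409 on the arrays of opposite dye. A probe effect need not change sign when the dyes are exchanged, so these correlations cannot decide on it. A response shared with the other 3 groups is argued against by a correlation of -0.641 that stayed in the residuals of 3082 genes after regression on those groups. Shortened RNA or cDNA in the low glucose sample of wild type stays open as a candidate explanation, since 670 genes of no list and uncalled in the other groups still had correlations of -0.679 and -0.618. A faster loss of long transcripts in wild type cells would give the same values and was not tested.

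At pH 8.0 the calcineurin medians were lower on arrays 1 and 2 than on arrays 3 and 4 both in snf1 (0.42 and 0.77 against 1.88 and 1.93) and in wild type (2.15 and 2.38 against 2.995 and 3.15). In snf1 general stress genes (1.97 and 1.93 against 1.05 and 1.19) and the 8 trehalose and glycogen genes with a value on all 8 arrays (2.72 and 2.48 against 1.78 on both) ran the other way, amino acid genes changed sign (-0.36 and -0.50 against 0.22 and 0.12), and a field of array 1 names snf11. A strain that kept SNF1 is argued against by SUC2 (0.55 on that array, 2.47 to 3.12 in wild type) and by HXT7 (-0.46, against 2.74 to 3.08). Both are preset genes, but they were picked for this check after their calls at pH 8.0, which use this array. Their lower calls in snf1 at low glucose come from other arrays. The planned test was the median of the 256 genes lower in snf1 at low glucose. It gave 0.739, below the lowest wild type array (0.809) by little more than the wild type SD (0.0542). A weaker alkaline response overall is argued against by slopes on the wild type mean of 0.75 and 0.74, against 0.75 and 0.71, a mean difference of 0.0159. A difference between days or cultures of the array pairs may account for the values and was not tested, since the labels give no batch.

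The 256 genes lower by at least 2-fold in snf1 at low glucose differed at pH 8.0 in their medians per array by -0.209 between genotypes (exact permutation p = 0.0286, the smallest possible, with the arrays taken as independent), and camera over 233 of them against all other genes gave p = 9.47e-16. Neither allows for their level in wild type, and the regression that does is given under the other observations.

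Single arrays lay far from the other 3 of their group in 4 of 183 sets of 4 values (2.19%). The limit used is one that about 1 in 20 groups of 4 independent normal values would pass, a rate not checked on these arrays. At pH 8.0, BOP2 was at 4.555 on wild type array 1 (others 3.81 to 3.89), TFS1 at 3.209 on wild type array 2 (others 2.86 to 2.91), RPL23A at 1.633 on wild type array 1 (others 1.20 to 1.26), and the median of the iron list at -0.028 on snf1 array 1 (others -0.18 to -0.16).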

How the results depend on the processing

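The random pair block, the removal of the gene length trend and the starvation genes within array pairs were chosen after seeing the data, and the other alternatives were planned. Among single gene results robust variances kept 599 of 599, while scaling left 511 the same, 82 weaker, 3 stronger and 3 reversed, averaging of consecutive arrays 437 the same and 135 weaker, the random pair block 558 the same and 41 weaker, length removal 562 the same, 36 weaker and 1 reversed, and leaving out 1 array 1781 the same, 292 weaker and 3 stronger. Leaving 1 array or 1 averaged value in a group assumes that it varies like the other groups. Signal over background was not used here, so its limit on weak genes is not known, and no gene had 2 values to choose between. Where no cause is named below, the cause was not tested.

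With arrays scaled to one spread, 2123 genes were called in wild type at low glucose (3405 without scaling), 467 in the difference at low glucose (1481; 439 shared) and, at pH 8.0, 20 higher and 20 lower in the difference (18 and 33). In that difference at low glucose, HXT6 turned to 0.0801 (adjusted p = 0.855), GSY1 to 0.2565 (0.83) and HXK1 to 1.8118 (0.0166). The scale factors there, 0.640 and 0.624 in wild type against 0.905 and 1.16 in snf1, turn genes raised alike in both genotypes higher in snf1. Among genes with a value on all 12 arrays, which are fewer, the counts were 1797 and 2071 in wild type at pH 8.0 and low glucose, and 84 in the difference at pH 8.0. With only the arrays of the comparison, which leaves fewer arrays for the variance, that difference had 30. With a 2-fold limit in addition to the adjusted p, counts were 682 and 464 at pH 8.0, 1666 and 495 at low glucose, 869 in the difference at low glucose and 278 raised by both stresses. With a 2-fold limit, one sign and no test they were 675, 459, 1670, 497, 900 and 279. With consecutive arrays averaged, which leaves fewer replicates, they were 1665 and 1246 at pH 8.0, 0 of 3723 in their difference (limma, 257 at an unadjusted p under 0.05), 803 in snf1 at low glucose, 610 in the difference there and 542 raised by both. With the array pair as a random block, 23 genes differed at pH 8.0, and 23 of these 23 were among the 51.

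With the length trend removed, FOX2 in wild type at low glucose turned to 0.4112 (adjusted p = 0.0322), and the starvation genes differed by -0.181 (exact permutation p = 0.0286). With an estimated correlation 26 of 150 list shifts were called, in place of 64 of 166, but 7 of the 26 had an estimate set to 0, under the preset value, and were not tested more strictly by it. With list medians set against those of 10000 random lists of the same size, 55 of 166 were called, and 49 of these were among the 64. Without 1 array, counts ranged from 2188 to 2527 and from 1887 to 2191 at pH 8.0 in wild type and snf1, and from 22 (without wild type replicate 4) to 161 (without snf1 replicate 3) in their difference, with 90 and 28 without wild type replicates 1 and 3. At low glucose they ranged from 2364 to 2549 in wild type and were 817 and 1047 without snf1 replicates 1 and 2. In the difference they ranged from 962 (without wild type replicate 2) to 1255, and for both stresses from 714 to 834. The starvation difference ranged from -0.1549 to -0.0849 for raised genes and from -0.0068 to 0.0778 for lowered genes. As a mean over the genes these were -0.1956 (exact permutation p = 0.0571) and 0.083 (exact p = 0.4), and over all called genes without a fold limit -0.0771 (exact p = 0.0571) and 0.0346 (exact p = 0.457).

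The replicate numbers are shared between genotypes. Deviations of same-numbered arrays from their group means at pH 8.0, with the dye effect left in, correlated by -0.0936, -0.369, -0.129 and 0.0970. By these values 0 of 4 arrays in each genotype lay nearest to their own number. The numbers were not read as pairs, but this check cannot decide it, since arrays 1 and 2 carry opposite dyes in wild type and snf1. At low glucose, where same-numbered arrays share their dyes, the correlation was 0.306. With the number as a block, 2494, 1965 and 50 genes were called at pH 8.0 in wild type, snf1 and the difference (26 shared), 3291, 1544 and 1358 at low glucose, and 835 in both. The starvation differences, -0.1175 and 0.041, cannot change under the block. An exact test that exchanges the signs of the differences between same-numbered arrays gave p = 0.25 and 0.625.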

Other observations

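The tests of the genes lower in snf1 at low glucose on the alkaline pH arrays, by medians, by camera and by regression, were chosen after the result was seen, and the overlap of the genotype differences was counted after seeing them.

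Part of the genes called lower in snf1 at pH 8.0 were also called lower at low glucose. Of 3231 genes with a tested difference in both conditions, 19 of the 26 lower in snf1 at pH 8.0 were also lower at low glucose, against 3.54 in independent lists (Fisher exact p = 6.52e-12). They include SUC2, HXT7, HXT4, JEN1, MPC3 and ALD4, with AEP1 and UGA2 beside these genes of sugar and organic acid use, and AIM17 and BDH2, which are among the largest rises at pH 8.0. When arrays were scaled, HXT4 lost its call at low glucose (adjusted p = 0.537) and ALD4 its calls in both (0.0719 at pH 8.0 and 0.0535 at low glucose). ALD4 also lost its call at pH 8.0 without wild type replicate 3 (0.0605) or 4 (0.0792) or snf1 replicate 1 (0.075) or 2 (0.0607), and HXT4 its call at low glucose without wild type replicate 2 (0.246) or snf1 replicate 2 (0.172) and with the array pair as a random block (0.0552). With consecutive arrays averaged, limma called 0 of 3723 genes at pH 8.0 (257 at an unadjusted p under 0.05), so no overlap could be counted. Higher in both were 6 of 12, among them ENP1, EXG1, SPB1 and UTP18, against 3.16 (Fisher exact p = 0.0935). None of the 26 was higher in snf1 at low glucose, against 6.86 (Fisher exact p = 0.000497). Genes are not independent replicates, so these p-values describe the genes measured.

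A hypothesis is that the genes needing SNF1 at low glucose are partly those needing it at pH 8.0. The 256 genes lower by at least 2-fold in snf1 at low glucose had medians at pH 8.0 of 0.866 ± 0.0542 (SD, n = 4 arrays) in wild type and 0.657 ± 0.0922 in snf1, a difference of -0.209. The exact permutation p was 0.0286, the smallest that 4 against 4 independent arrays can give (2 against 2 averaged pairs give no less than 0.333), and camera over 233 of the genes against all others gave p = 9.47e-16. Neither test allows for the level in wild type. A weaker alkaline response overall in snf1 may account for this difference. Over 3723 genes the snf1 arrays followed the wild type mean with slopes of 0.71 to 0.75, and 202 genes of the set departed from that regression by medians of -0.003 to -0.087 (mean -0.0381). These are negative on all 4 arrays but small beside the difference. Error in the wild type mean lowers such slopes and makes such departures smaller, and it was not allowed for. By this regression the difference is not shown to be particular to these genes, nor is it shown not to be, and the hypothesis stays open.

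The calcineurin list varied between arrays of the same group at pH 8.0. Its medians on arrays 1 to 4 were 2.15, 2.38, 2.995 and 3.15 in wild type and 0.42, 0.77, 1.88 and 1.93 in snf1, so arrays 3 and 4 were higher in both genotypes. PHO89 was at 3.86, 4.30, 5.01 and 5.12 in wild type and at -0.17, -0.34, 1.27 and 1.00 in snf1. At low glucose in wild type, PHO84 (1.18) and ENA1 (1.71) had a value on 1 array each.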
